A study of Mus musculus with 4 samples.

How the data were processed

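The series holds 4 RNA-seq libraries from primary mouse aortic smooth muscle cells, 2 from mice with a smooth muscle deletion of Yap1 and Wwtr1 and 2 from wild-type mice, taken 18 days after tamoxifen. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with a stranded total RNA kit. The submitters' processing notes list FastQC, STAR 2.5.2b, featureCounts 1.5.1 (Subread) and DESeq2 1.14.1 and the mouse build mm10/GRCm38, without their roles. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Reads that fit several genomic places, such as those of paralogs and pseudogenes, may have been left out or shared.

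The authors deposited 1 table with 1 column per library, and its name describes the values as normalized counts. The values are whole numbers, yet they are not raw counts: whole numbers are skipped at a fixed spacing in the knockout columns and doubled at a fixed spacing in the wild-type columns, as division by a size factor and rounding give. The unit of the deposited table was therefore taken as a score, a normalized read count rounded to whole numbers. The spacing gave estimated size factors of 0.887 and 0.890 in the knockout and 1.10 and 1.16 in the wild-type libraries. In 4 simulated libraries the method missed the true factor by at most 0.04%. In the knockout columns, where these factors skip 45 and 44 whole numbers up to 400, every value up to 400 can be reached. In the wild-type columns no whole number is skipped, so the check says nothing there. The rounding hides which of 2 neighbouring read numbers lies behind some wild-type values, so no count model was used and the tests run on logarithms. The estimated reads on genes were 12290000 and 11810000 in the knockout and 15620000 and 16810000 in the wild-type libraries, so the knockout libraries were the shallower. All 37 mitochondrial genes were listed at 0 in all 4 libraries, so nothing is said here of mitochondrial RNA. All 4 libraries expressed Y-linked genes (Ddx3y from 1915 to 2231 normalized counts) and little Xist (11 to 18), so a mix of sexes between the groups was not seen.

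The table was analysed in R 4.3.3 with limma 3.58.1, as had been planned for normalized values, before the data were examined. Values were transformed to log2(value + 1) and genes with a mean of at least 10 over the 4 libraries were kept. The group was the single term, and eBayes was run with an intensity trend, which moderates each gene's variance towards that of genes of similar expression (3.96 prior degrees of freedom beside 2 residual ones). P-values are two-sided with Benjamini-Hochberg adjustment over the 15058 genes, and the threshold was an adjusted p of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. SDs are over the 2 libraries of a group on the count scale, and SEs are limma's on the log2 scale. For a group at 0, the fold is a lower bound on the ratio of summed counts, taken against 3 counts over the group. It covers counting error only, not the spread between libraries.

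The 30 gene lists were fixed before the data were examined: contractile, actin and focal adhesion, YAP/TAZ target, Hippo, osteochondrogenic, calcification inhibitor, Wnt, BMP and TGF-β, matrix, inflammation, interferon, cell cycle, p53, stress and metabolic genes, and markers of other cell types. All members were found in the table by symbol, older symbol or identifier except Rn7sl1 and Kcnq1ot1. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, which does not compare a set with other genes. A list's score in a library is the mean log2(value + 1) over its tested members. Gene positions and overlaps come from GENCODE M21 on GRCm38, in which 99.0% of the tested genes were found by identifier.

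The named genes follow a rule fixed with the lists. It takes Yap1 and Wwtr1, then the 12 rising and 12 falling genes with the largest log2 fold change among those past the threshold. These must have a mean of at least 50 in the higher group and groups that do not overlap, and predicted genes without a proper name are skipped. It also takes the up to 4 members of each list with the smallest p, and a set of smooth muscle, bone, Wnt and inflammation genes chosen in advance. Some of them are left unnamed for length.

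The test was tried on simulated data with 200 changed genes. Every gene had the same dispersion of 0.00546, the median of the estimates within the groups of these libraries. Each estimate rests on 2 libraries, and the median of such estimates tends to lie below the typical dispersion. Differences in spread between genes and shared shifts from the mix of cells were left out. For both reasons the rates may flatter the test. It recovered 27.0% of genes changed 1.5-fold, 79.5% of those changed 2-fold (3 false calls, 1.9%) and 94.0% of those changed 4-fold, with 0 calls where nothing was changed. When 1 simulated library was left out, limma made 0 calls at each of these folds, so a call lost in this way says little about a gene. The simulation held 200 changed genes, while limma gave 4898 genes of the data an unadjusted p under 0.05. The adjustment depends on that share, so these simulated refits need not carry over to the data. The alternatives were other pseudocounts, filters and scalings, no intensity trend, the replicate number as a block, each library left out, and other thresholds. The pair of planned count models (quasi-likelihood and negative binomial) was not run, since the values are not counts.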

Results

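RNA was sequenced from primary smooth muscle cells isolated from the mouse aorta, the contractile cells of the vessel wall, 18 days after tamoxifen. In the knockout mice, the genes for the transcriptional co-activators YAP (Yap1) and TAZ (Wwtr1), the effectors of the Hippo pathway, were inactivated in smooth muscle. There were 2 knockout and 2 wild-type libraries. The deposited table held 39179 genes, of which 15367 were at 0 in all 4 libraries, and 15058 with a mean normalized read count of at least 10 were tested. The normalized counts summed to 13861333 and 13279332 in the knockout and 14235444 and 14519178 in the wild-type libraries. From the steps between the rounded values, the reads on genes were estimated at 12290000 and 11810000 in the knockout and 15620000 and 16810000 in the wild-type libraries. The labels do not say that the 2 libraries of a group came from different animals, so p-values measure only the spread between these samples, which may be technical.

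The targeted genes were examined first, as a check of the labels. Yap1 (chromosome 9, 7931999 to 8004596, minus strand, GRCm38) had normalized counts of 947 and 962 in the knockout and 1966 and 1877 in the wild-type libraries, a log2 fold change of -1.01 (SE 0.10, limma adjusted p = 0.0080, n = 2 per group). Wwtr1 (chromosome 3, 57455649 to 57575910, minus strand) had counts of 2848 and 2466 against 3423 and 4016. Its log2 fold change of -0.48 (SE 0.13) missed the threshold at a limma adjusted p of 0.055, which was 0.0486 after rescaling by TMM factors and 0.0483 after quantile normalization, although both knockout values lay below both wild-type values. Counts over a whole gene include reads outside a deleted part, so the remaining reads do not measure the remaining protein. The adjusted p of Yap1 was 0.0815 without a filter on low counts and 0.0745 without an intensity trend. It was 0.156 and 0.209 without knockout replicates 1 and 2, 0.132 without wild-type replicate 1 and 0.0475 without wild-type replicate 2, with log2 fold changes from -1.04 to -0.97.

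**Figure D1:**
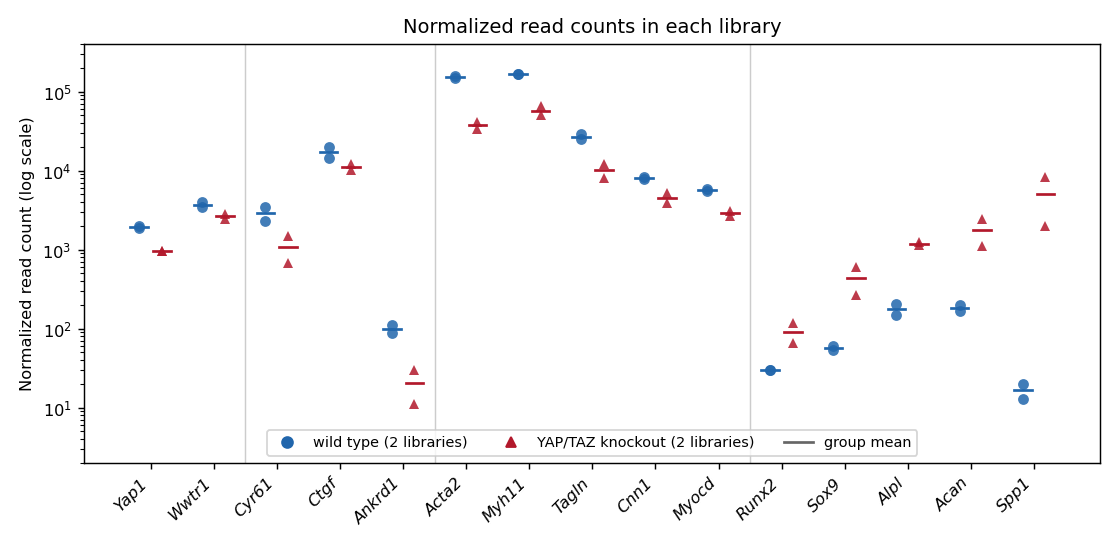
Normalized read counts (log axis) of 15 genes in the 2 wild-type (circles) and 2 YAP/TAZ knockout (triangles) libraries, with a line at each group mean; vertical lines part the targeted genes, YAP/TAZ targets, contractile genes and osteochondrogenic genes. Acta2 lies at 157904 and 150117 in the wild type and at 41201 and 33544 in the knockout, and Spp1 at 13 and 20 against 1979 and 8269.

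The comparison of knockout with wild type asked which transcripts of aortic smooth muscle cells depend on YAP and TAZ. At a limma adjusted p under 0.05, 1443 genes were higher and 1009 lower in the knockout, 1108 and 447 of them by at least 1 on the log2 scale. The libraries of the 2 groups did not overlap for any of these 2452 genes, but the threshold itself favours such genes. Over all tested genes the groups did not overlap for 62.8%, where chance gives an expected 33.3%. Genes that vary together can share 1 split of the libraries, so this excess is not a test of a group effect. These calls rested on the choice of test: limma called 0 genes without the filter on low counts (5472 at an unadjusted p under 0.05, smallest adjusted p 0.0710) and 0 without the intensity trend (4274, smallest adjusted p 0.0643), against 4898 at an unadjusted p under 0.05 in the test used. Leaving out knockout replicate 1, knockout replicate 2 or wild-type replicate 1 also left 0 calls (3792, 3228 and 2671 at an unadjusted p under 0.05), and leaving out wild-type replicate 2 left 587 higher and 153 lower genes.

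Genes of the contractile apparatus were lower in the knockout. Of 24 tested contractile smooth muscle genes, 17 fell and 2 rose, with a median log2 fold change of -0.98, and 19 fell and 2 rose when adjusted over the list alone. Mylk4, a myosin light chain kinase family member, had 1057 ± 47.4 (SD, n = 2) normalized counts in the knockout and 14156 ± 891 in the wild type, a 13.4-fold difference (log2 fold change -3.74, SE 0.10, limma adjusted p = 0.000496). Acta2, which encodes smooth muscle α-actin (chromosome 19, 34241090 to 34255590), fell from 154011 ± 5506 to 37373 ± 5414 (log2 fold change -2.05, SE 0.16, adjusted p = 0.0053 by limma). The regulatory light chain Myl9 fell with a log2 fold change of -1.79 and Kcnmb1, a subunit of the large-conductance potassium channel, with one of -1.33. Among the genes chosen in advance, the values were -1.55 for the smooth muscle myosin heavy chain Myh11, -1.44 for Tagln, -0.83 for Cnn1 and -0.97 for Myocd, a co-activator of smooth muscle genes, and all 4 passed. In the annotation, an opposite-strand gene overlaps at least 20% of the exon length of Tagln, whose reads may then be shared. The 2 members that rose, named after their values were seen, were Mustn1 (log2 fold change 1.33) and Actg2 (0.60), which encodes the γ-actin of smooth muscle. Without wild-type replicate 2 limma called 7 contractile genes lower, and without any other single library 0. In simulated data, with fewer changed genes, refits with 1 library left out found no gene changed 4-fold. Calls lost in such refits, here and in the lists below, therefore say little about a gene. In the same knockout libraries, 19 of 20 macrophage, 12 of 18 adipocyte and 8 of 17 endothelial markers were higher, so a fall within the cells is not separated here from a changed mix of cells.

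Genes of the actin cytoskeleton and focal adhesions moved mostly in the same direction: 15 of 27 fell and 3 rose, and 16 fell and 4 rose when adjusted over the list alone. Zyx, which encodes the focal adhesion protein zyxin, had a log2 fold change of -1.40 (SE 0.10), the tropomyosin gene Tpm1 -1.45 (SE 0.14) and Lpp -1.36 (SE 0.15). The risers, named after their values were seen, were Actg1, Itga5 and Tpm4. The count of falling genes was 5 without wild-type replicate 2 and 0 without any other single library. In the same knockout libraries, 19 of 20 macrophage markers were higher.

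Of 25 genes listed in advance as YAP/TAZ targets, 8 fell, 1 rose and 16 did not pass; 10 fell and 5 rose when adjusted over the list alone. The count that rose depended on the scaling: 3 rose and 8 fell after quantile normalization, and 5 rose and 7 fell after rescaling to the same total. The list median of -0.20 reached -0.07 in other settings. The 4 with the smallest p all fell: Crim1 (log2 fold change -1.12, SE 0.13), Fjx1 (-1.53, SE 0.26), Lats2 (-0.77, SE 0.13), which encodes a kinase that inhibits YAP and TAZ, and Ajuba (-1.25, SE 0.24). Of the well-known targets, Cyr61 (Ccn1) went from 2902 ± 817 (SD, n = 2) to 1080 ± 578 normalized counts, a log2 fold change of -1.51 (SE 0.39, limma adjusted p = 0.0493), and Ankrd1 had one of -2.37 (SE 0.52, limma adjusted p = 0.033). Ctgf (Ccn2) had 17314 ± 3815 in the wild type and 11123 ± 1283 in the knockout and missed the threshold (limma adjusted p = 0.066). Nuak2, the member that rose, was named after its values were seen (log2 fold change 2.39). Reads of Lats2 and Ctgf may be shared with an annotated gene that overlaps at least 20% of their exon length. Whichever library was left out, limma called no target lower, and it called 1 higher without wild-type replicate 2. The fall of targets stands beside the rise of 19 of 20 macrophage, 12 of 18 adipocyte and 8 of 17 endothelial markers in the same libraries, and a changed mix of cells is not separated from it here. In the Hippo pathway core, Lats2 and the transcription factor gene Tead3 (-0.72, SE 0.15) fell and the other 20 of 22 members did not pass, and both calls were lost whichever library was left out.

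Osteochondrogenic genes, which bone and cartilage cells express, rose in part: 8 of 22 tested members rose, 1 fell (Sox6, named after its values were seen) and 13 did not pass, and 11 rose and 2 fell when adjusted over the list alone. At the same total 11 rose. Alpl, which encodes the phosphatase that permits mineral deposition (chromosome 4, 137741733 to 137796384), had 1132 and 1233 normalized counts in the knockout and 148 and 206 in the wild type, a 6.73-fold rise (log2 fold change 2.75, SE 0.19, limma adjusted p = 0.0048). Spp1, which encodes the secreted protein osteopontin and is also expressed by macrophages (chromosome 5, 104435118 to 104441050), had 1979 and 8269 against 13 and 20, the largest rise in log2 fold change of the genes named by the rule (7.88, SE 0.64). The cartilage proteoglycan gene Acan rose with a log2 fold change of 3.18 (SE 0.35) and the chondrogenic transcription factor gene Sox9 with one of 2.79 (SE 0.38). Runx2, a transcription factor of bone formation, was at 65 and 118 against 30 and 30 (1.52, SE 0.39, limma adjusted p = 0.049), and Bmp2 had a log2 fold change of 0.89 (SE 0.19). The count of rising members was 4 without wild-type replicate 2 and 0 without any other single library. In the same libraries 19 of 20 macrophage (median 2.86), 12 of 18 adipocyte and 5 of 20 fibroblast markers were higher, so the cells that express these genes are not identified.

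Of 10 tested genes that restrain calcification, 6 rose and none fell, and 7 rose and 1 fell when adjusted over the list alone. Tnfrsf11b, which encodes osteoprotegerin, had a log2 fold change of 2.49 (SE 0.30) (5.63-fold). Mgp, the matrix Gla protein gene, rose 2.20-fold, with 20240 ± 1986 normalized counts in the knockout and 9196 ± 1182 in the wild type (SD, n = 2). The pyrophosphate transporter gene Ank had a log2 fold change of 0.67 and Ahsg, at 44 and 42 against 6 and 5 counts, one of 2.76. With wild-type replicate 2 left out, limma called 1 inhibitor higher, and with any other library left out 0. The same rises in macrophage (19 of 20), adipocyte (12 of 18) and fibroblast (5 of 20) markers stand beside these.

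Genes of Wnt signalling moved in both directions. Of 17 tested β-catenin targets and feedback genes, 4 rose and 2 fell; 4 rose and 3 fell when adjusted over the list alone. The adhesion receptor gene Cd44 rose with a log2 fold change of 1.48 (SE 0.17), Wisp1 (Ccn4) with 1.87 (SE 0.22) and Ccnd1, which encodes cyclin D1 and shares at least 20% of its exon length with an opposite-strand gene, with 1.98 (SE 0.36). The feedback inhibitor gene Nkd1 fell (-1.23, SE 0.21). Axin2, the feedback gene used most often as a reporter of the pathway, was at 147 and 153 against 160 and 125 (log2 fold change 0.08, SE 0.22, limma adjusted p = 0.83), and Lef1, at 2 and 10 against 3 and 2, was below the filter. Among 30 ligands, receptors and transducers, 5 rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone. The receptor gene Fzd8 fell (-2.08, SE 0.17), while Frzb (1.68, SE 0.19) and Sfrp4 (2.62, SE 0.34), which encode secreted Wnt antagonists, and Rspo3 (1.39, SE 0.28), which encodes a Wnt agonist, rose. The Dishevelled genes did not pass, with log2 fold changes of 0.07 for Dvl1, -0.50 for Dvl2 and -0.23 for Dvl3. Without wild-type replicate 2, limma called 3 targets higher and 0 lower, and 3 pathway members higher and 1 lower; without any other single library it called 0. Macrophage (19 of 20, median 2.86) and fibroblast markers (5 of 20, median 1.22) were higher in the same libraries, so these changes are not assigned to smooth muscle cells. The fibroblast median ran from 0.61 to 1.81 when 1 library was left out.

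Of 35 extracellular matrix genes, 12 rose and 1 fell (Ltbp1, named after its values were seen), and 18 rose and 1 fell when adjusted over the list alone. After quantile normalization 19 rose, and at the same total 17. Versican (Vcan) had a log2 fold change of 1.32 (SE 0.15), Fbln2 2.16 (SE 0.28), Lum, which also stands among the fibroblast markers, 2.14 (SE 0.29) and Col8a1 2.55 (SE 0.40). Among 26 genes of BMP and TGF-β signalling, 4 rose and 3 fell; 6 rose and 3 fell when adjusted over the list alone, and 7 rose and 2 fell after rescaling to the same total. The risers included Chrdl1 (1.68), which encodes a BMP antagonist, and the co-receptor gene Eng (0.79). Without wild-type replicate 2, limma called 11 matrix and 2 BMP or TGF-β genes higher and none lower, and without any other library it called 0. The score of the fibroblast markers, their mean log2 value, was 11.7 and 11.5 in the knockout and 9.89 and 11.0 in the wild type.

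Genes of inflammation and of the interferon response were higher in the knockout. By the rule for the largest changes over all genes, Spp1 was followed by Cd300lf, a myeloid receptor gene (90 and 535 normalized counts in the knockout, 0 and 3 in the wild type), the cytokine gene Il6 (41 and 759 against 0 and 2) and Nos2, which encodes inducible nitric oxide synthase (151 and 616 against 1 and 9). Clec4e was at 0 in both wild-type libraries and at 17 and 230 in the knockout (log2 fold change 6.01, SE 1.28). Its summed count was at least 82.3-fold higher against a floor of 3 counts over the group, and most of that sum came from knockout replicate 2. Lcn2, an acute phase gene, followed at 151 and 325 against 2 and 3. The knockout libraries differed from each other by several-fold in most of these genes. Of 28 genes of inflammation and chemokines, 17 rose and none fell, with a median log2 fold change of 2.58, and 21 rose when adjusted over the list alone. Macrophage markers moved with them (19 of 20 rose, median 2.86): the inflammation score minus the macrophage score, taken after the results were seen, was -2.07 and -1.23 in the knockout and -1.44 and -1.86 in the wild type. After Lcn2 the smallest p belonged to the chemokine genes Cxcl12 (3535 and 5537 against 973 and 1283), Ccl8 (136 and 205 against 4 and 14) and Cxcl13 (48 and 144 against 2 and 2). Of 24 interferon response genes, 14 rose and none fell, and 16 rose when adjusted over the list alone, led by Oas2 (log2 fold change 2.73, SE 0.31), Oasl2 (1.99), Irf7 (1.97) and Ifi44 (2.80). The mean log2 value of the inflammation list was 7.03 and 8.52 in the knockout and 4.39 and 5.27 in the wild type. Without wild-type replicate 2, limma called 6 inflammation and 2 interferon genes higher, and without any other library 0.

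The largest falls lay in genes of several kinds. Tnni3k, which encodes a cardiac kinase, was at 0 in both knockout libraries and at 43 and 58 in the wild type, at least 33.7-fold lower against a floor of 3 counts over the group. The P-cadherin gene Cdh3 was at 3 and 16 against 315 and 357, the myosin-binding protein gene Mybpc2 at 3 and 3 against 149 and 130, and Ptprz1, which encodes a receptor tyrosine phosphatase, at 857 and 525 against 11638 and 11745. Ptprz1 (chromosome 6, 22875502 to 23052916) thus fell 17.4-fold (log2 fold change -4.12, SE 0.22, limma adjusted p = 0.0041).

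Of 26 cell cycle genes, 17 rose and none fell, with a median log2 fold change of 2.36, and 23 rose when adjusted over the list alone. Top2a, the topoisomerase of dividing cells, was at 879 and 1248 against 68 and 165, a 9.80-fold rise (log2 fold change 3.29, SE 0.42, limma adjusted p = 0.010), and Ccna2, Mki67 and Kif11 had log2 fold changes of 2.38, 3.29 and 2.61. Macrophage markers rose more in the same libraries: the cell cycle score minus the macrophage score, also taken after the results were seen, was -1.95 and -1.99 in the knockout and -0.73 and -1.25 in the wild type. With 12 of 18 adipocyte, 8 of 17 endothelial and 5 of 20 fibroblast markers also higher, the dividing cells are not identified. Of 18 genes of the p53 response, Plk2 (2.44) and Pmaip1 (3.62) rose and the death receptor gene Fas (-1.07) fell, with the same counts when adjusted over the list alone. In the list for the unfolded protein and integrated stress responses, 9 of 17 genes rose and none fell, and 12 rose when adjusted over the list alone. They included the chaperone genes Pdia4 (0.91, SE 0.13) and Hspa5 (0.85, SE 0.13), the transcription factor gene Xbp1 (0.76) and the asparagine synthetase gene Asns (2.30). Immediate early genes, which tissue dissociation can induce, gave 6 rises among 22, over all genes and when adjusted over the list alone, led by Junb (2.13), Klf4 (1.59), Egr2 (1.97) and Egr3 (2.11). Of 17 hypoxia and glycolysis genes, Ldha (0.97) and Pfkfb3 (0.80) rose, both also when adjusted over the list alone. None of 23 nuclear genes of oxidative phosphorylation passed in limma on either adjustment, and 1 had an unadjusted p under 0.05 (Uqcrfs1, 0.50, SE 0.17, limma adjusted p = 0.10). Of 13 nuclear-retained or non-polyadenylated RNAs, Rpph1 rose (0.93), whose reads may be shared with an overlapping gene, and Rn7sk fell (-1.30, SE 0.33), with the same counts when adjusted over the list alone. With wild-type replicate 2 left out, limma called 5 cell cycle, 1 p53, 2 stress response, 1 immediate early and 1 hypoxia gene higher, and 1 nuclear-retained or non-polyadenylated RNA higher and 1 lower, and with any other library left out 0.

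Markers of other cell types differed between the groups. Of 20 macrophage markers, 19 rose and all 20 passed when adjusted over the list alone, with a median log2 fold change of 2.86. Cx3cr1 was at 276 and 592 against 24 and 42, Laptm5 at 789 and 1477 against 72 and 158, C1qc at 462 and 464 against 65 and 124 and Emr1 (Adgre1, F4/80) at 505 and 764 against 56 and 126. Of 18 adipocyte markers, 12 rose and Plin4 fell (15 and 1 when adjusted over the list alone), with Pparg at 303 and 316 against 73 and 109 and Cidec at 1272 and 1441 against 124 and 375. Of 17 endothelial markers, 8 rose (16 over the list alone), led by Flt1 and Pecam1, and of 20 fibroblast and adventitial markers 5 rose (13 over the list alone), led by Lum and Ly6a. After quantile normalization 10 endothelial and 10 fibroblast markers rose, and at the same total 11 and 9. Pericyte markers split, with Notch3 (-1.19) and Mcam (-0.75), which smooth muscle also expresses, lower and Steap4 (2.37) and Anpep (1.19) higher among 11; 2 rose and 3 fell when adjusted over the list alone. Of 12 neural and Schwann cell markers, Ncam1 fell and 2 rose, among them Scn7a (7 rose and 1 fell over the list alone). Actc1 and Neb rose among 14 skeletal and cardiac muscle markers, Il7r among 6 lymphocyte markers (3 over the list alone) and Pf4 among 4 erythroid and platelet markers. Neither Cdh1 nor Krt18, the 2 tested mesothelial and epithelial markers, passed in limma, and 0 had an unadjusted p under 0.05. Without wild-type replicate 2, limma called 14 macrophage, 12 adipocyte, 8 endothelial, 14 fibroblast, 3 pericyte, 2 neural, 1 muscle, 0 lymphocyte and 0 erythroid markers changed, and without any other library 0. The 2 wild-type libraries also differed from each other: replicate 2 exceeded replicate 1 by 1.29 in the macrophage score, 1.20 in the adipocyte, 1.11 in the fibroblast and 0.88 in the endothelial score, all log2.

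**Figure D2:**
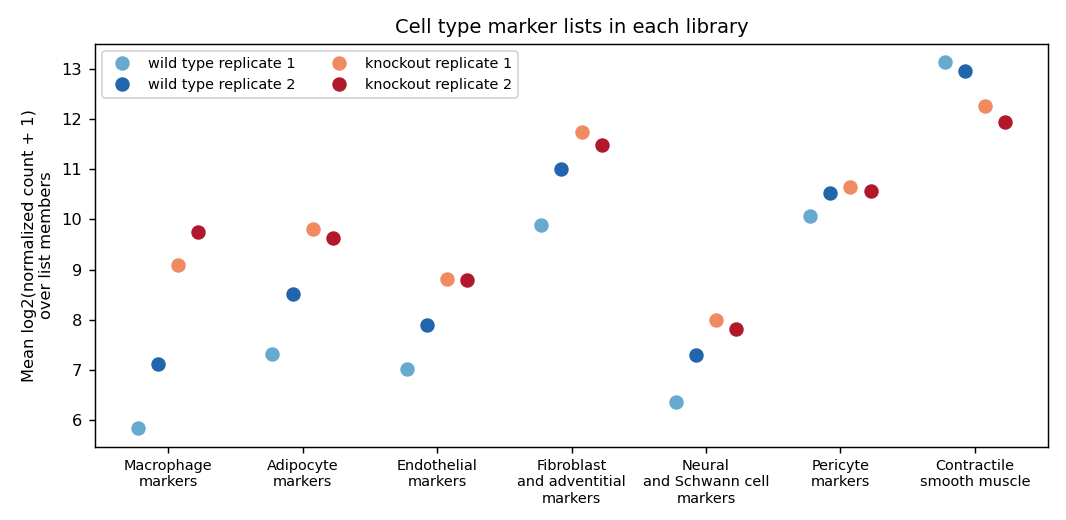
Mean log2(normalized count + 1) over the tested members of 6 lists of markers of other cell types and of the contractile list, with 1 point per library (2 wild type, 2 knockout). The macrophage score lies at 9.10 and 9.75 in the knockout and at 5.84 and 7.13 in the wild type, and the contractile score at 12.25 and 11.95 against 13.13 and 12.96.

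Set tests were run on 28 of the 30 lists fixed in advance; the mesothelial list had too few tested genes and the mitochondrially encoded list none. With camera at a preset correlation of 0.01, 16 lists passed an adjusted p of 0.05. With an estimated correlation none of the 28 passed (smallest adjusted p = 0.606). That test rests on 2 residual degrees of freedom and had little power, so it does not show that no list changed. The estimated correlations ran from -0.05 (p53) to 0.90 (fibroblast). For lists with a high estimate, such as cell cycle (0.80), macrophage (0.85) and contractile genes (0.61), the p-values at 0.01 may be far too small. At the preset correlation, contractile genes (adjusted p = 6.6e-07) and genes of the actin cytoskeleton and focal adhesions (0.0017) were lower than other genes. Those higher were cell cycle (8.1e-10), macrophage (1.3e-09), inflammation (1.9e-08), interferon (4.8e-07), endothelial and unfolded protein response (both 1.6e-06), adipocyte (4.8e-05), matrix (7.4e-05), fibroblast (0.00010), neural (0.010), calcification inhibitor (0.013), immediate early (0.021), osteochondrogenic (0.031) and BMP and TGF-β (0.041) genes. The actin list gave 0.062 after quantile normalization, and after rescaling to the same total the osteochondrogenic list gave 0.071 and the BMP and TGF-β list 0.058. Leaving out knockout replicate 1 gave 0.075 for the osteochondrogenic and 0.068 for the neural list, and leaving out knockout replicate 2 gave 0.079 for calcification inhibitors, 0.17 for BMP and TGF-β genes and 0.17 for immediate early genes. Without wild-type replicate 1 the BMP and TGF-β list gave 0.19, and without wild-type replicate 2 the immediate early list 0.27. Lists that passed only with a library left out were oxidative phosphorylation (0.013, without knockout replicate 2) and lymphocyte markers (0.016, without wild-type replicate 2), both higher. The direction test of fry passed for 0 lists (smallest adjusted p = 0.0947) and its test for change in either direction for 19. The YAP/TAZ targets did not pass camera (adjusted p = 0.15), nor did the Wnt targets (0.28). For the pericyte and the skeletal and cardiac muscle lists, the median (0.09 and -0.12) and the direction of the test (down and up, adjusted p = 1.00 and 0.48) differed in sign. The medians themselves ran from -0.05 to 0.35 and from -0.28 to 0.93 when 1 library was left out, so their sign rests on single libraries.

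**Figure D3:**
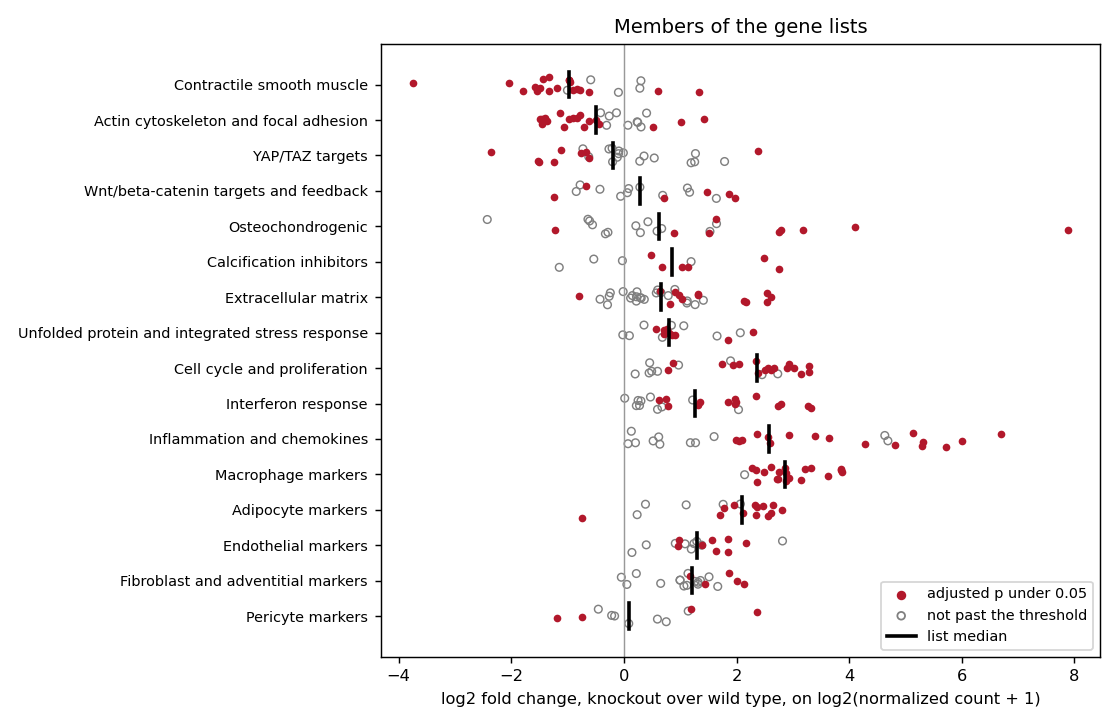
Log2 fold change, knockout over wild type, of every tested member of 16 gene lists, from 2 libraries per group; filled points passed a limma adjusted p of 0.05, open points did not, and the bar is the list median. The contractile median lies at -0.98, the YAP/TAZ target median at -0.20 and the macrophage median at 2.86.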

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

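All alternatives were planned before the data were examined, apart from list medians without each library and the gene families. The calls depended on 2 choices of the test. Without the filter on low counts (23812 genes fitted), 0 genes were higher and 0 lower, and 0 YAP/TAZ targets, 0 contractile, 0 osteochondrogenic and 0 Wnt target genes passed in limma, with 5472 genes at an unadjusted p under 0.05. Without the intensity trend all these counts were again 0, with 4274 at an unadjusted p under 0.05. The log2 fold change of Yap1 stayed at -1.01 in both, with adjusted p of 0.0815 and 0.0745; the range over the refits of Yap1 was 0.0034 to 0.209. The cause was not tested. All 2452 genes kept their direction in every refit that held them (2218 of 2218 with a mean of at least 50), but only the 3 other scalings could have turned it. The filter, the intensity trend and the replicate block leave the fold change as it is. Another pseudocount or leaving out 1 library cannot turn a gene whose groups do not overlap. Leaving out 1 library gave 0 to 587 higher and 0 to 153 lower genes, 0 YAP/TAZ targets lower, 0 to 7 contractile genes lower, 0 to 4 osteochondrogenic genes and 0 to 3 Wnt targets higher, and a log2 fold change of Yap1 from -1.04 to -0.97. The calls came without wild-type replicate 2 and were 0 without any other library; 649 of those 740 genes were among the 2452. With 1 library in a group and 1 residual degree of freedom, the lone library is assumed to vary like the others, and the same refit of simulated data found no gene changed 4-fold.

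Wwtr1 passed after rescaling by TMM factors (log2 fold change -0.49, adjusted p = 0.0486) and quantile normalization (-0.42, 0.0483); its adjusted p over the refits ran from 0.0483 to 0.281, and the cause was not tested. An adjusted p under 0.1 gave 2209 higher and 1653 lower genes, and a log2 fold change of at least 1 left 447 lower genes, 5 YAP/TAZ targets and 10 contractile genes, by the construction of these thresholds. Other pseudocounts gave 1421 to 1501 higher and 994 to 1044 lower genes, a mean of at least 50 gave 1267 and 1030, TMM factors 1495 and 1077, quantile normalization 1516 and 1257, and the same total in each library 1831 and 854 (68.2% higher, against 58.8%). With the replicate block, 1823 genes were higher and 1213 lower, and 2419 of the 2452 were among them. It gave 10 falling and 3 rising YAP/TAZ targets, 2 and 7 calcification inhibitors and 3 and 9 BMP and TGF-β genes. Same-numbered libraries deviated together with a correlation of 0.118 across genes, which with only 2 pairs does not show that the numbers pair the libraries. The planned edgeR and DESeq2 fits were not run, because rounding hides the read numbers behind some wild-type values.

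Sign changes were confined, among the named genes and these refits, to genes that did not pass. Quantile normalization gave log2 fold changes of -0.043 for Alas2, -0.23 for Itga2b and -0.06 for Axin2. Without each library in turn, Krt18 ranged from -1.27 to 0.15, Hbb-bs from -0.43 to 1.89, Alas2 from -0.051 to 0.36, Itga2b from -0.23 to 0.42, Axin2 from -0.093 to 0.26 and Dvl1 from -0.036 to 0.17; the cause was not tested. At this depth and with 2 libraries per group, 27.0% of simulated 1.5-fold changes were found, so a gene that missed the threshold is not shown to be unchanged.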

Other observations

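The tests of the ratios of marker scores, the gene families and the further gene lists were chosen after the main results were seen, although the values of the further lists had not been; the tests of scaling, length, further lists, wild-type adipocyte counts and chance had their outcomes set out beforehand. Families were formed by the start of the symbol. Among serpins, inhibitors of proteases, 11 of 22 rose and none fell, led by Serpina3n (3652 and 3614 normalized counts in the knockout, 88 and 223 in the wild type) and Serpinb1a (log2 fold change 2.68). Of 17 C-type lectins, many of them myeloid receptors, 11 rose and none fell, and of 36 collagens 14 rose and 1 fell. Of 328 zinc finger genes named Zfp, 23 fell and 7 rose (1009 and 1443 of 15058 over all genes), with a median log2 fold change of -0.24. The number falling was 42 after quantile normalization and 16 at the same total. More genes rose than fell, too, among CC chemokines (6 of 12), CXC chemokines (5 of 10), kinesins (11 of 32, with 2 falling), tubulins (5 of 14), cathepsins (5 of 11) and histones (5 of 21). None of 76 cytosolic ribosomal protein genes passed in limma. More genes fell than rose among potassium channel subunits (7 of 45, with 3 rising), Hox genes (3 of 26, with 1 rising) and Frizzled and Wnt genes (3 of 17, with 1 rising). Their median log2 fold changes were 0.08, -0.25 and 0.06. None of them passed camera at the preset correlation (camera adjusted p = 0.95, 0.11 and 0.95), so a lean towards falling is not shown. Of 28 integrins 6 rose and 7 fell, but 6 rose and 4 fell after quantile normalization, and 7 and 6 at the same total. In the other families named here with calls, the side with more genes passing stayed the same under the 3 other scalings. Without wild-type replicate 2, limma called 5 serpins, 7 lectins, 10 collagens and 2 zinc finger genes higher and none lower. It then also called 3 CC and 2 CXC chemokines, 4 kinesins (and 1 lower), 2 tubulins, 4 cathepsins and 0 histones higher, and without any other library 0 in any family. With camera, 10 of 19 families passed at the preset correlation (serpins, lectins and zinc finger genes at an adjusted p of 2.9e-06). None passed with an estimated one (smallest adjusted p = 0.465), which rests on 2 residual degrees of freedom and had little power.

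Other abundant genes with large changes, named after their values were seen, include the acute phase gene Hp (2242 and 3849 against 73 and 236), Timp1 (743 and 2313 against 42 and 67), which encodes an inhibitor of matrix proteases, the stromelysin gene Mmp3 (4277 and 6068 against 283 and 594) and the transcription factor gene Runx1 (665 and 1339 against 94 and 141). The imprinted RNA H19 was at 189 and 730 against 23 and 49. On the falling side were Npnt (5536 and 5766 against 21767 and 22540), which encodes an integrin ligand, Adamts8 (292 and 218 against 1955 and 1766) and Tub (395 and 447 against 2222 and 2478). Of 18 circadian clock genes, 1 rose (Bhlhe40, log2 fold change 1.79) and none fell, with a median of -0.16 that ran from -0.38 to 0.11 when 1 library was left out.

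Contractile smooth muscle genes were lower in the knockout. A lower share of smooth muscle cells as the whole cause would raise the markers of every other type alike, if smooth muscle cells do not express them. The macrophage minus fibroblast score was -2.64 and -1.72 in the knockout against -4.05 and -3.87 in the wild type. Its gap of 1.23 lay beside a largest range within a group of 0.92. This departs from such a shared rise only if smooth muscle cells express neither marker set. If part of the fibroblast signal came from smooth muscle cells, a lower share would raise the macrophage score more. The gap alone therefore does not decide the question. The macrophage minus endothelial score also parted the groups (0.28 and 0.96 in the knockout, -1.18 and -0.77 in the wild type). So did the adipocyte minus fibroblast score (-1.92 and -1.84 against -2.57 and -2.48). Their gaps of 1.06 and 0.56 lay beside largest ranges within a group of 0.68 and 0.09. The endothelial minus fibroblast score overlapped between the groups, as a shared rise would give (-2.92 and -2.68 in the knockout, -2.87 and -3.10 in the wild type). The authors' scaling is argued against: under the 3 other scalings at least 16 members still fell. So is a trend with transcript length: once the trend was removed the median of the list was -1.14, against -0.98 before. For genes that only smooth muscle cells express, a lower share would give 1 common fall. Over the 24 tested members the log2 fold changes had an SD of 1.00 beside a median SE of 0.16, and 2 rose. This argues against a lower share as the only cause in this list, though members that other cells also express would spread as well. A loss of smooth muscle share as part of the cause, together with more leukocytes, stays open. So does an effect of the deletion on the cells' contractile genes, which stays a hypothesis.

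Macrophage markers were higher in the knockout. The same gap of 1.23 in the macrophage minus fibroblast score argues against more adventitia as the whole cause only if both marker sets come from adventitia alone. In the wild type the fibroblast score was already 9.89 and 11.0, against 5.84 and 7.13 for macrophages. If part of the fibroblast signal has another source, the same added tissue would raise the macrophage score more. The gap therefore does not decide the question. Perivascular fat, with the macrophages it holds, cannot be told apart as a cause: the gap in the macrophage minus adipocyte score was 0.68, less than the largest range within a group of 0.83. More macrophages or other leukocytes in the knockout preparations may account for the rise, since 96.7% of 30 further leukocyte genes had a log2 fold change above 1 (24 rose, 29 when adjusted over the list alone). Whether they lay in the vessel wall or came with the preparation, or whether smooth muscle cells themselves expressed such genes, was not tested.

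Adipocyte markers were higher in the knockout. More perivascular fat carried over in the knockout preparations may contribute: the median log2 fold change of 27 further adipocyte genes was 1.43 (16 rose, 20 when adjusted over the list alone), with Pck1 at 3916 and 3492 against 284 and 986. The wild-type libraries also differed from each other, by 1.20 in the adipocyte score. An adipocyte programme switched on in knockout smooth muscle cells stays open too: 13 of 18 markers reached 50 normalized counts in both wild-type libraries, but that shows a baseline and not the source of the rise.

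With 2 libraries in each group there are 3 ways to split the 4 libraries, too few for a share under 0.05. The real split gave 2452 genes, 1 of the 3 splits (the real one itself) gave as many, and the highest of the other splits gave 0. Each of the other splits puts 1 knockout and 1 wild-type library in each group. The difference between knockout and wild type then adds to the spread within groups, so few calls could be made.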
